A study of Mus musculus with 18 samples.

How the data were processed

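RNA of mouse bone marrow-derived macrophages was measured on 18 single-colour Agilent arrays, 1 per sample, in 6 groups of 3. The groups cross 2 genotypes (Irf4+/- and Irf4-/-) with 3 culture conditions (mock for 18 h, IL-4 for 4 h and IL-4 for 18 h), and the letters A, B and C name 3 experiments. Groups and letters were taken from the sample titles.

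Per the file headers, the authors scanned each array and extracted its spots with Agilent Feature Extraction 9.5.1, which gave each spot an intensity after background subtraction, with spatial and multiplicative detrending and a surrogate value for very small signals, and no scaling between arrays. The deposited array files also hold each spot's mean intensity, the median intensity of its local background, and the software's flags for control spots, outliers, saturation and signal well above background. A deposited table of the whole series holds log2 values, and how the authors made it is not given in the sources used here. Each of its columns matched the log2 intensity minus the array's 75th percentile minus the same value of the Irf4+/- mock array of its letter (lowest correlation 0.9993 over 15243 bright probes). The medians of its columns lay between -0.18 and 0.21, and the 3 Irf4+/- mock columns were 0 throughout, so that table has no spread between those mock arrays.

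Of 43379 spots per array that are not controls, 63.4% to 74.4% were well above background, and between 63 and 182 carried an outlier flag. The 75th percentile of the intensity lay between 719.6 and 1971.8. The number of arrays, 3 per group, limits the precision of every comparison.

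From the intensities, log2 was taken and the array's 75th percentile was subtracted; all log2 levels below are on that scale. Control spots and spots flagged as outliers were left out, spots of 1 probe were averaged, and saturated spots were kept. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 27505 probes. Of 41174 probes, 22951 were named through their RefSeq accession, 6622 through a current symbol in the array file, 2977 through a synonym of 1 gene and 1881 by the file's own name, and 6743 had no symbol. Of 21140 named genes, 15378 were tested, each by its kept probe with the highest mean signal. Among 77 named called results with other kept probes, 1 had a probe of the opposite sign and 19 had a probe whose log2 change was over 1.5 times larger or smaller; where such a value is printed, the other probe stands beside it. Where a gene was not well above background on any array of a group, the fold is given as "at least", against the mean of each array's lowest signal well above background or the probe's own signal, whichever was higher.

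Tests used limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 mean per group over all 18 arrays, moderated tests (lmFit, eBayes) and Benjamini-Hochberg adjustment over the genes tested; a gene was called at an adjusted p under 0.05. All p-values are two-sided, and errors beside a log2 change are standard errors of that fit with 3 arrays per group. The contrasts were each IL-4 time against mock in each genotype, the genotypes against each other in each condition, the difference of the IL-4 response between genotypes at each time, and 18 h against 4 h in Irf4+/- cells. Groups of genes were 36 lists, tested with camera at a preset correlation between genes of 0.01 and adjusted over the lists of a contrast; camera compares a list with all other genes. Genes with a value missing on any array, Cxcl11 among the list members, were left out of the list tests, and Cxcl11 counts in the medians of its list except where an alternative is named. Beside each list test stand a repeat with the correlation estimated from the data and, where named, fry, which asks whether a list's genes move on balance 1 way. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read files and draw plots.

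The lists were the IL-4 signature, JAK-STAT feedback and cytokine receptors, the IRF family, MHC class II presentation, MHC class I presentation, costimulation, inflammatory cytokines and chemokines, interferon-stimulated genes, chemokine receptors and migration, C-type lectins and scavenger receptors, Toll-like receptors and adaptors, cholesterol biosynthesis, lipid uptake and fatty acid oxidation, glycolysis, oxidative phosphorylation, arginine and polyamine metabolism, DNA replication, mitosis, CDK inhibitors, ribosome biogenesis and Myc targets, the unfolded protein response, the NRF2 response, lysosome, macrophage identity, markers of monocytes, conventional and plasmacytoid dendritic cells, B-lineage cells, T and NK cells, neutrophils, basophils with mast cells and eosinophils, erythroid cells, osteoclasts and fibroblasts, immediate early with heat shock genes, and sex-linked genes. Groups, contrasts, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes of a contrast are the 12 largest rises and 12 largest falls among called genes with 1 sign in all 3 experiments and an ordinary symbol. To these come up to 4 called members of each list (the 2 brightest members where fewer than 2 were called) and 18 fixed genes: Irf4, Arg1, Retnla, Chil3, Mrc1, Mgl2, Ccl17, Ccl22, Ccl24, Cdh1, Socs1, Cish, Pdcd1lg2, Ciita, H2-Aa, Cd74, Myc and Pparg (Ccl22 was not among the genes tested). A gene outside that rule is said to have been chosen after its values were seen.

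The series design states that each experiment used littermates, so a letter marks a shared experiment across groups. Deviations of arrays from their group means correlated between groups of 1 letter with a median r of 0.631 (lowest 0.432, all 45 pairs above 0, across genes), against a median of -0.418 between letters. The letters therefore paired the samples, and the fit with the letter as a block (the blocked fit) was the alternative of a fixed design without it. Arrays lay on 7 slides and were scanned on 3 days, with gaps of 219 and 236 days. The Irf4-/- arrays of experiment A were scanned on day 1, the Irf4+/- arrays of A and all of C on day 2, and all of B on day 3.

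Alternatives were normexp background correction (offset 50), quantile and median scaling, the authors' deposited log2 table, other filters on dim probes, other probe rules, blocks for letter, pool of cells, slide and scan day, an intensity trend, array weights, only the groups of a contrast, and leaving out each array in turn. Added after the data were seen were normexp without spots at least 50 intensity units dimmer than their local background, slide as a random block, experiment A left out, the same with the block, and the block together with an estimated correlation. The steps were tested on simulated data for the genotype contrast at 18 h (15326 genes, 200 changed). Without the block, 24% of genes changed by log2 1 and 73% of those changed by log2 2 were recovered with 0 false calls. With the block, 67% and 87% were recovered with 3 false calls. The simulated arrays held additive effects of the letter and independent noise, with no effect of pool or slide. They follow the model of the blocked fit, so its false calls there do not show how it behaves in these data. Positions are those of the array files, which do not name their genome build. No reference genome was used.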

Results

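Bone marrow-derived macrophages of Irf4-/- mice and Irf4+/- littermates on the C57BL6/J background were kept for 18 h without IL-4 (mock), or with IL-4 at 10 ng/ml for 4 h or 18 h. The control genotype is heterozygous, cells of several animals were pooled per sample, and mock is 18 h only, so the 4 h response is read against an 18 h mock. Changes are log2 with their standard error from 3 arrays per group, and a gene rose or fell when its adjusted p in limma was under 0.05 among 15378 genes. The errors are those of the fit without the block, also where an adjusted p with the block stands beside them. Values with normexp are those of the planned correction. Up to 8 spots per array far dimmer than their local background drew its fit. With those spots left out no value reversed, as given below.

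The signal of the Irf4 probe was no lower in samples labelled Irf4-/- than in Irf4+/- samples. In mock cells it was -1.11 ± 0.72 (log2, SD, n = 3) in Irf4+/- and -0.78 ± 0.22 in Irf4-/-, a difference of 0.33 ± 0.39 (adjusted p = 1). After 4 h of IL-4 it was 1.67 ± 0.59 and 1.72 ± 0.33, and after 18 h it was 1.26 ± 0.47 and 1.52 ± 0.55. Irf4 encodes a transcription factor of lymphocytes and IL-4-treated macrophages, and its signal rose with IL-4 in Irf4+/- cells by 2.78 ± 0.39 at 4 h (adjusted p = 7.55e-04) and 2.37 ± 0.39 at 18 h (adjusted p = 0.00209). In Irf4-/- samples it rose by 2.50 ± 0.39 (adjusted p = 0.00174) and 2.30 ± 0.39 (adjusted p = 0.00332). The array holds 1 Irf4 probe, and where it lies relative to the deleted part of the gene is not given in the sources used here, so this signal does not test the genotype labels and does not measure the protein.

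In Irf4+/- macrophages, 4 h of IL-4 raised Retnla by 11.54 ± 0.59 (adjusted p = 1.19e-07, at least 980-fold), which encodes a secreted protein of alternatively activated macrophages. Arg1, whose enzyme splits arginine into ornithine and urea, rose by 8.74 ± 0.74 (adjusted p = 9.51e-06). The transcription factor genes Msx3 (7.54 ± 0.71) and Gata3 (7.42 ± 1.38, at least 70.4-fold) rose. So did Cish (6.92 ± 0.94) and Socs1 (5.93 ± 0.68), whose proteins brake JAK-STAT signalling. Cdh1, encoding E-cadherin, rose by 6.50 ± 0.87 and Pdcd1lg2, encoding the PD-1 ligand PD-L2, by 6.36 ± 0.54. Edn1, encoding endothelin 1, rose by 6.19 ± 1.21 (at least 51.9-fold). Among the falls were Cx3cr1, the fractalkine receptor gene (-3.81 ± 0.81, adjusted p = 0.0135, -2.45 on its other kept probe), and Nfkbiz, a cofactor of NF-kB (-3.75 ± 0.53). The neutrophil chemokine gene Cxcl1 (-3.63 ± 0.91) and Tal2 (-3.54 ± 0.39) fell too. Slc40a1, encoding the iron exporter ferroportin, fell by 3.27 ± 0.59, Fos by 2.77 ± 0.43, Tnf by 2.67 ± 0.58 and the lipoprotein sensor gene Tlr2 by 2.65 ± 0.40. Of the fixed genes, the chemokine gene Ccl24 (4.96 ± 0.98) and the lectin genes Mgl2 (4.29 ± 0.33) and Mrc1 (1.49 ± 0.36) rose. Ciita (0.92 ± 0.76) was called with the experiment as a block but not without it (adjusted p = 0.77, 0.0143 with the block). Myc (1.54 ± 0.99), Chil3 (1.12 ± 1.02), Ccl17 (0.79 ± 0.71), Pparg (0.19 ± 0.27), Cd74 (0.11 ± 0.55) and H2-Aa (0.09 ± 0.89) were not called. Altogether 654 genes changed, 355 up and 299 down, and 474 of them at least 2-fold. The share of rises was 54.3%, and 65.9% with median scaling (313 and 162). The count was 2803 with the block, 209 with only these groups in the fit and 5058 with slide as a random block. It was 435 without the IL-4 array of A and 424 without the mock array of C.

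The IL-4 signature rose as a group at 4 h in Irf4+/- cells (22 of 40 members rose, 26 adjusted over the list alone, median 1.90). Its adjusted p was 1.83e-32, and adjusted p = 0.0011 with an estimated correlation. Chemokine receptors fell with it (5 of 21 members, 7 adjusted over the list alone, median -0.70, adjusted p = 1.02e-06 and 0.00369 with an estimated correlation). Cx3cr1, the formyl peptide receptor gene Fpr1 (-2.41 ± 0.41) and Ccr2 (-1.80 ± 0.43) were among them. Ribosome biogenesis and Myc targets, which supply ribosomes for growth, lay higher in all 22 members (median 0.85, adjusted p = 7.08e-08, but adjusted p = 0.499 with an estimated correlation). Of these, 2 rose (4 adjusted over the list alone), the helicase gene Ddx21 by 1.25 ± 0.33. Inflammatory cytokines lay lower (5 of 20 fell, 9 adjusted over the list alone, median -0.76, adjusted p = 4.25e-04). So did Toll-like receptors (median -0.13, 5 of 21 fell, Tlr2 and Cd14 first, adjusted p = 0.00626). These lists had adjusted p = 0.38 and adjusted p = 0.381 with an estimated correlation. The NRF2 response lay lower too (median -0.39, adjusted p = 0.00626, but adjusted p = 0.444 with an estimated correlation), and Hmox1 fell by 1.29 ± 0.23. The unfolded protein response lay higher (median 0.31, adjusted p = 0.00328), and Pdia4 rose by 1.60 ± 0.27. Arginine metabolism was also higher (median 0.11, adjusted p = 0.0308), and in it Arg1 and the arginine transporter gene Slc7a2 rose. The last 2 lists had adjusted p = 0.381 with an estimated correlation. Oxidative phosphorylation (median 0.26, adjusted p = 0.00626), DNA replication (-0.41, adjusted p = 0.00626) and mitosis (-0.36, adjusted p = 0.0104) had no member called. For each of them adjusted p = 0.963 with an estimated correlation.

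**Figure D1:**
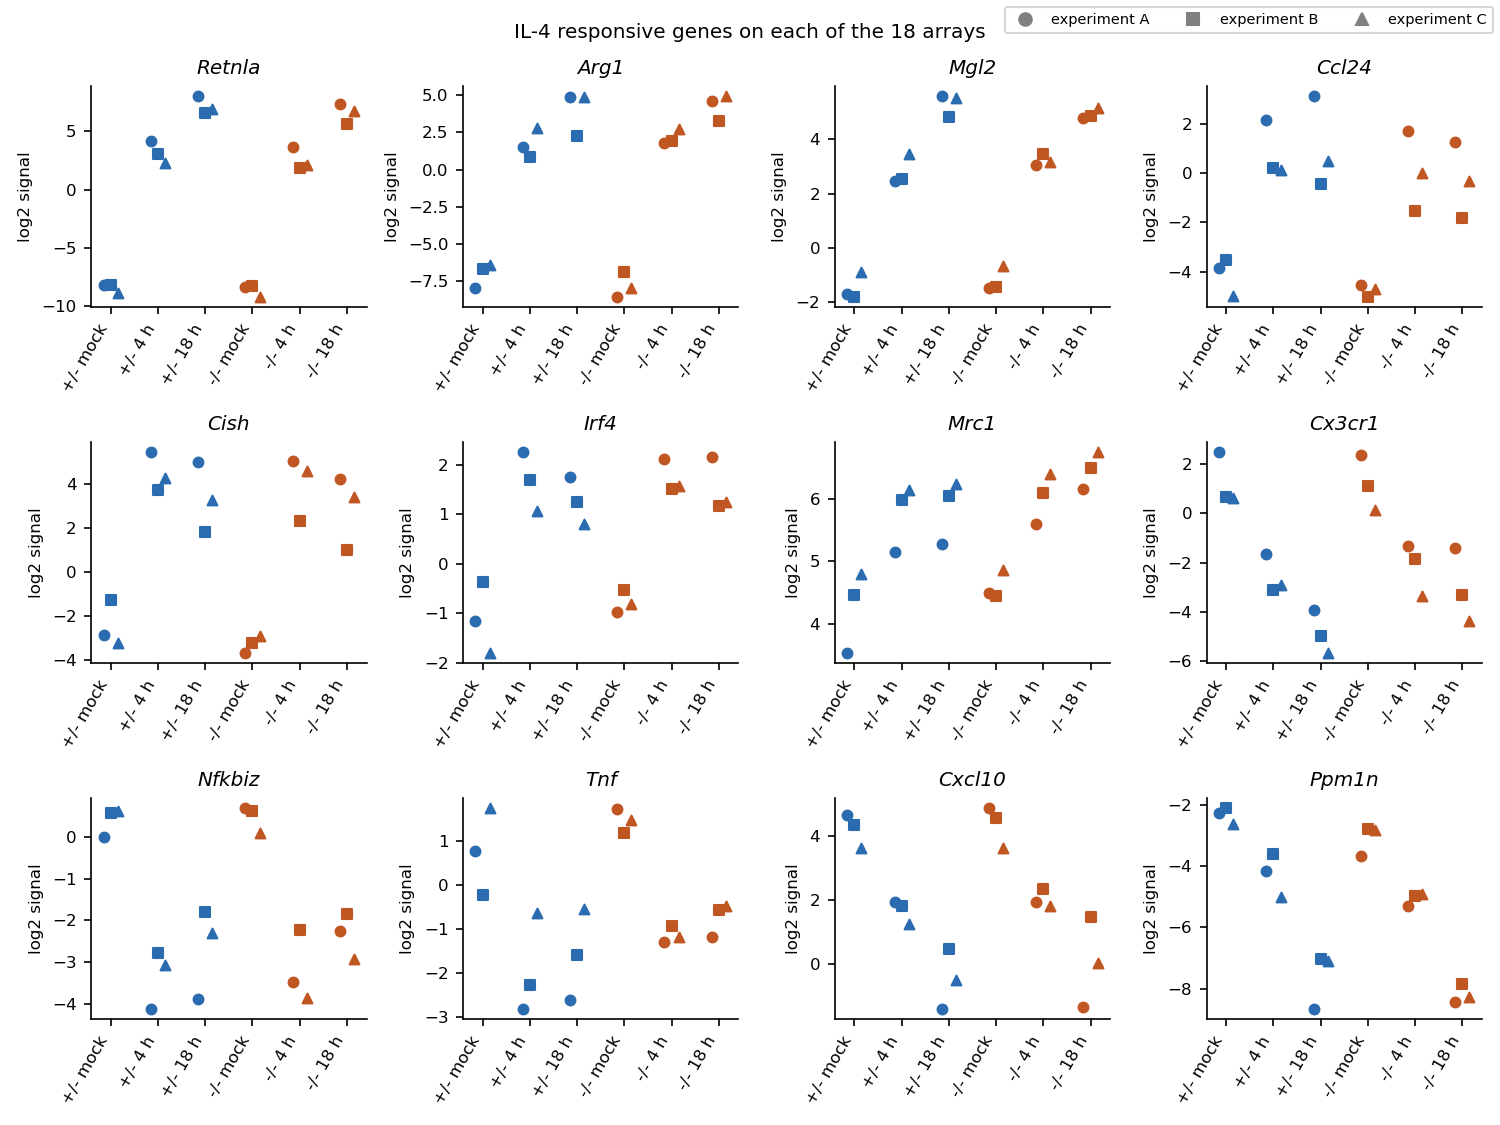
Log2 signal of 12 genes on each of the 18 arrays (minus the array's 75th percentile), by genotype and condition. Each symbol is 1 array, and its shape marks the experiment.

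After 18 h in Irf4+/- cells, Retnla stood 15.54 ± 0.59 above mock (adjusted p = 1.79e-09, at least 15600-fold) and Arg1 10.99 ± 0.74 (adjusted p = 7.37e-07). Rnase2a, encoding a ribonuclease of the eosinophil family, rose by 8.29 ± 1.75, Msx3 by 7.25 ± 0.71 and the sodium channel gene Scn3a by 7.02 ± 0.38 (at least 36.6-fold). The galactose lectin gene Mgl2 rose by 6.78 ± 0.33 and the water channel gene Aqp3 by 6.64 ± 0.71. Of the fixed genes, Cish (5.82 ± 0.94), Pdcd1lg2 (5.77 ± 0.54), Cdh1 (5.46 ± 0.87), Ccl24 (5.19 ± 0.98), Socs1 (4.38 ± 0.68) and Mrc1 (1.59 ± 0.36) rose. Pparg, encoding a nuclear receptor of lipid metabolism, rose by 1.25 ± 0.27. Cx3cr1 fell by 6.09 ± 0.81 (adjusted p = 4.21e-04, -2.71 on its other kept probe), the phosphatase gene Ppm1n by 5.26 ± 0.42 and the interferon-induced chemokine gene Cxcl10 by 4.66 ± 0.59. The activating receptor genes Cd300e and Pilrb1 fell by 4.42 ± 0.34 and 4.25 ± 0.25, and Gpr84, encoding a fatty acid receptor, by 4.04 ± 0.48. Chil3 (3.36 ± 1.02, adjusted p = 0.0928, 2.22e-04 with the block) and Ciita (1.67 ± 0.76, adjusted p = 0.389, 2.9e-04 with the block) were called with the experiment as a block but not without it. The same held for Cd74 (1.26 ± 0.55, adjusted p = 0.356, 2.76e-04 with the block) and H2-Aa (0.80 ± 0.89, adjusted p = 0.972, 0.00511 with the block). Ccl17 (0.55 ± 0.71) and Myc (1.43 ± 0.99) were called in neither fit. Altogether 637 genes changed, 325 up and 312 down, 484 of them at least 2-fold. The share of rises was 51.0%, and 42.4% with normexp (103 and 140). The count was 2386 with the block, 166 with only these groups in the fit, 4049 with the pool of cells as a random block and 407 without the IL-4 array of A.

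Interferon-stimulated genes, the antiviral genes driven by type I interferon, lay below mock in all 41 members after 18 h in Irf4+/- cells (median -1.51). As a group they had adjusted p = 4.82e-21, but adjusted p = 0.343 with an estimated correlation. Of these, 5 fell over all genes (20 adjusted over the list alone, 32 over all genes with the block). Isg20 fell by 2.88 ± 0.60 and Isg15 by 2.29 ± 0.60, next after Cxcl10. Inflammatory cytokines lay lower (9 of 20 fell, 12 adjusted over the list alone, median -1.56, 0.043 with normexp, adjusted p = 2.09e-08 and 0.0438 with an estimated correlation). That call was lost with block and estimated correlation together (adjusted p = 0.366). After Cxcl10 and Cxcl1 came the T-cell chemokine genes Cxcl11 (-3.60 ± 0.47, at least 7.70-fold lower) and Cxcl9 (-3.34 ± 0.50, at least 7.05-fold lower), and with normexp Cxcl1 (0.38), Cxcl11 (1.03) and Cxcl9 (1.05) turned. These genes did not reverse with normexp once the spots far dimmer than their local background were left out. Chemokine receptors fell too (6 of 21 fell, median -0.82, adjusted p = 6.62e-06 and 0.00768 with an estimated correlation), and the integrin gene Itgax rose by 2.87 ± 0.23 (1.56 on its other kept probe). The IL-4 signature rose (26 of 40, 29 adjusted over the list alone, median 2.41, adjusted p = 4.9e-39 and 4.45e-04 with an estimated correlation). Osteoclast markers, shared by fusing macrophages, lay higher (median 1.20, adjusted p = 0.00126, but adjusted p = 0.0539 with an estimated correlation). Ocstamp (3.40 ± 0.83, 6.47 on its other kept probe), the proton pump gene Atp6v0d2 (3.12 ± 0.29) and Itgb3 (2.98 ± 0.42, 1.63 on its other kept probe) rose. Oxidative phosphorylation lay higher in all 34 members (median 0.38, -0.08 with normexp, adjusted p = 6.56e-06, but adjusted p = 0.759 with an estimated correlation). Lipid uptake (median 0.25, -0.025 with normexp, adjusted p = 0.0133) and the unfolded protein response (median 0.23, -0.18 with normexp, adjusted p = 0.0137) were higher, and Ppargc1b rose by 1.78 ± 0.29. Both lists had adjusted p = 0.399 with an estimated correlation. Immediate early genes lay higher (median 0.22, where the test turned to a fall with normexp, adjusted p = 0.0336), and Ier3 rose by 2.95 ± 0.41. That call was lost with an estimated correlation (adjusted p = 0.206 with an estimated correlation) and with the block (adjusted p = 0.0801 with the block). Arginine metabolism was higher (median 0.14, -0.27 with normexp, adjusted p = 0.041, but adjusted p = 0.351 with an estimated correlation). Toll-like receptors were lower (median -0.036, mean -0.47, 5 fell, adjusted p = 0.0015), as was mitosis (median -0.36, adjusted p = 0.00683). They had adjusted p = 0.219 and adjusted p = 0.91 with an estimated correlation. MHC class II genes had a median of 0.51 (adjusted p = 0.442, 0.0178 with the block, 0.475 with block and estimated correlation) and were called under 4 of 22 alternatives.

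Between 4 h and 18 h of IL-4 in Irf4+/- cells, the matrix gene Fn1, encoding fibronectin, rose by 4.02 ± 0.88 (adjusted p = 0.0407) and Retnla by a further 3.99 ± 0.59 (adjusted p = 0.00308). The Wnt receptor gene Fzd1 rose by 3.79 ± 0.56, the fatty acid carrier gene Fabp4 by 2.56 ± 0.52, Mgl2 by 2.49 ± 0.33 and Itgax by 2.29 ± 0.23 (1.27 on its other kept probe). Wdr86 fell by 3.60 ± 0.66 and Asb2 by 3.44 ± 0.33. The protease inhibitor genes Serpina3f and Serpina3g fell by 3.58 ± 0.40 and 3.33 ± 0.39. Il4ra, encoding the IL-4 receptor chain, fell by 1.76 ± 0.33 (adjusted p = 0.0156). Arg1 (2.25 ± 0.74, adjusted p = 0.215, 0.0402 with the block), Chil3 (2.23 ± 1.02, 0.007 with the block) and Socs1 (-1.55 ± 0.68, 0.0199 with the block) were called with the block but not without it. Cd74 (1.14 ± 0.55, 0.00123 with the block), Pparg (1.06 ± 0.27, 0.0142 with the block) and H2-Aa (0.70 ± 0.89, 0.0163 with the block) behaved likewise. Osteoclast markers lay higher (median 1.05, adjusted p = 2.68e-05 and 0.0161 with an estimated correlation), and Atp6v0d2 rose by 2.13 ± 0.29. Immediate early genes lay higher (median 0.54, adjusted p = 1.33e-04 and 0.0161 with an estimated correlation), and Fos rose by 2.21 ± 0.43. Costimulation genes lay lower (median -0.76, adjusted p = 2.33e-04 and 0.0161 with an estimated correlation), and Tnfsf14 fell by 1.74 ± 0.25 and Cd40 by 1.64 ± 0.37. JAK-STAT genes lay lower too (median -0.26, adjusted p = 0.00469 and 0.0262 with an estimated correlation). With block and estimated correlation together these 4 calls were lost (adjusted p = 0.0682 for costimulation and adjusted p = 0.151 for the others).

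Interferon-stimulated genes lay lower at 18 h than at 4 h in all 41 members (median -1.35, 2 fell, 10 adjusted over the list alone, adjusted p = 2.53e-21, but adjusted p = 0.436 with an estimated correlation). Ribosome biogenesis lay lower in all 22 (median -0.59, adjusted p = 1.05e-06) and inflammatory cytokines in 13 of 20 (median -0.26, adjusted p = 0.0328). They had adjusted p = 0.763 and adjusted p = 0.693 with an estimated correlation. Lipid uptake was higher (median 0.29, adjusted p = 2.68e-05, but adjusted p = 0.129 with an estimated correlation). The NRF2 response was higher (median 0.13, -0.12 with normexp, adjusted p = 0.0344, but adjusted p = 0.775 with an estimated correlation), and Hmox1 rose by 1.60 ± 0.23. DNA replication (median 0.30, where the test turned to a fall with normexp, adjusted p = 0.0344) and lysosome genes (median 0.18, -0.21 with normexp, adjusted p = 0.0428) were higher. MHC class I genes were lower (median -0.18, adjusted p = 0.0344). The last 3 lists had adjusted p = 0.956 with an estimated correlation. MHC class II (median 0.64, adjusted p = 0.197, 0.00259 with the block) and oxidative phosphorylation (median 0.18, -0.083 in B, -0.17 with normexp, adjusted p = 0.109, 0.0131 with the block) were called with the block but not without it, and neither with block and estimated correlation (adjusted p = 0.438 and 0.927). MHC class II was called under 6 of 22 alternatives. Inflammatory cytokines and the NRF2 response lost their calls with it (adjusted p = 0.0916 each with the block). Altogether 177 genes changed, 82 up and 95 down. The share of rises was 46.3%, 36.1% with median scaling (44 and 78) and 28.6% with normexp (4 and 10). The count was 1770 with the block, 0 with only these groups in the fit and 3552 with the pool of cells as a random block. Without 1 array it was 88 to 117 (4 h A 88, B 117 and C 88, 18 h A 103, B 113 and C 99).

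In Irf4-/- macrophages 4 h of IL-4 raised Retnla by 11.14 ± 0.59 (adjusted p = 1.95e-07, at least 593-fold) and Arg1 by 9.92 ± 0.74 (adjusted p = 2.58e-06, at least 447-fold). Msx3 rose by 8.51 ± 0.71 (at least 149-fold), Cish by 7.25 ± 0.94, Pdcd1lg2 by 6.92 ± 0.54, the Ras activator gene Rasgrp1 by 6.86 ± 0.59 (2.56 on its other kept probe) and Cdh1 by 6.29 ± 0.87. Ciita (0.89 ± 0.76) was called with the block but not without it (adjusted p = 0.725, 0.0176 with the block). Cxcl1 fell by 3.75 ± 0.91, Nfkbiz by 3.69 ± 0.53, Nap1l2 by 3.44 ± 0.48, Cx3cr1 by 3.37 ± 0.81 (-2.34 on its other kept probe) and Tnf by 2.60 ± 0.58. The IL-4 signature rose (21 of 40, 26 adjusted over the list alone, median 1.73, adjusted p = 7.73e-28 and 0.00227 with an estimated correlation). Chemokine receptors fell (4 of 21, 6 adjusted over the list alone, median -0.47, adjusted p = 1.99e-06 and 0.00449 with an estimated correlation). Ribosome biogenesis lay higher in all 22 members (median 0.79, adjusted p = 3.96e-07, but adjusted p = 0.708 with an estimated correlation), and Pes1 rose by 0.72 ± 0.16. DNA replication lay lower in all 34 (median -0.54, adjusted p = 2.34e-05), and mitosis lay lower as well (median -0.33, adjusted p = 0.00428). Both had adjusted p = 0.94 with an estimated correlation. Inflammatory cytokines (median -0.62, 5 fell, 8 adjusted over the list alone, adjusted p = 7.2e-04) and Toll-like receptors (median -0.13, 5 fell, adjusted p = 0.00978) lay lower, and arginine metabolism higher (median 0.18, adjusted p = 0.0237). For each of these adjusted p = 0.409 with an estimated correlation. The NRF2 response was lower (median -0.33, adjusted p = 0.0108, but adjusted p = 0.666 with an estimated correlation). Calls added with the block were interferon-stimulated genes (median -0.21, adjusted p = 0.0313 with the block), cholesterol biosynthesis (-0.21, adjusted p = 0.0431 with the block) and oxidative phosphorylation (0.19, adjusted p = 0.0175 with the block). With block and estimated correlation these were lost (adjusted p = 0.977 each), and the median of interferon-stimulated genes was 0.074 in C, with 17 of 41 members below 0. Altogether 605 genes changed, 345 up and 260 down, 441 of them at least 2-fold. The share of rises was 57.0%, and 71.0% with normexp (157 and 64). The count was 2807 with the block, 221 with normexp and 5357 with the pool of cells as a random block. It was 383 and 287 without the IL-4 arrays of A and C, and 341 and 377 without the mock arrays of B and C.

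After 18 h in Irf4-/- cells Retnla had risen by 15.15 ± 0.59 (adjusted p = 2.56e-09, at least 9560-fold) and Arg1 by 12.07 ± 0.74 (adjusted p = 2.82e-07, at least 1990-fold). Msx3 rose by 8.23 ± 0.71 (at least 123-fold), the tight junction gene Cldn11 by 7.12 ± 0.61, Scn3a by 6.77 ± 0.38 (at least 30.3-fold), Mgl2 by 6.14 ± 0.33 and Mrc1 by 1.87 ± 0.36. Ppm1n fell by 5.09 ± 0.42 (at least 11.3-fold), Cxcl10 by 4.28 ± 0.59, Cx3cr1 by 4.22 ± 0.81 (-2.60 on its other kept probe) and Gpr84 by 4.02 ± 0.48. Nox1, encoding a superoxide-producing oxidase, fell by 3.38 ± 0.47 and Acod1, whose enzyme makes itaconate, by 3.37 ± 0.38. Chil3 (2.96 ± 1.02, adjusted p = 0.164, 6.51e-04 with the block) and Pparg (1.02 ± 0.27, adjusted p = 0.0513, 0.0123 with the block) were called with the block but not without it. So were Cd74 (1.11 ± 0.55, adjusted p = 0.42, 7.8e-04 with the block) and Ciita (0.82 ± 0.76, adjusted p = 0.75, 0.0273 with the block). The IL-4 signature rose (23 of 40, 29 adjusted over the list alone, median 2.38, adjusted p = 4.04e-29 and 0.00184 with an estimated correlation). Chemokine receptors fell (6 of 21 fell, 1 rose, median -0.63, adjusted p = 6.83e-05 and 0.0173 with an estimated correlation). Interferon-stimulated genes lay lower in all 41 members (median -1.39, adjusted p = 1.9e-23, but adjusted p = 0.4 with an estimated correlation). Of these, 5 fell (17 adjusted over the list alone, 30 over all genes with the block). Inflammatory cytokines lay lower as well (median -1.20, 6 fell, 11 adjusted over the list alone, adjusted p = 2.86e-07, but adjusted p = 0.0711 with an estimated correlation). Mitosis was lower (median -0.42, adjusted p = 3.05e-05) and oxidative phosphorylation higher in all 34 members (median 0.39, adjusted p = 0.00172). Both had adjusted p = 0.96 with an estimated correlation. Osteoclast markers lay higher (median 0.38, adjusted p = 0.0283, but adjusted p = 0.273 with an estimated correlation), and Itgb3 and Atp6v0d2 rose. Toll-like receptors tested lower with a median of 0.071 and a mean of -0.32 (adjusted p = 0.0147, but adjusted p = 0.402 with an estimated correlation), and Tlr2, Cd14 and Tlr5 fell. With the block osteoclast markers (adjusted p = 0.164) and Toll-like receptors (adjusted p = 0.0512) lost their calls and DNA replication (median -0.18, 0.022 in A) was called lower (adjusted p = 0.0345, but adjusted p = 0.837 with block and estimated correlation). Altogether 552 genes changed, 333 up and 219 down, 437 of them at least 2-fold, and the median of all genes was 0.12. The share of rises was 60.3%, 54.5% with quantile normalization and 68.3% with normexp. The count was 2862 with the block, 142 with normexp and 5596 with the pool of cells as a random block. It was 314 and 348 without the mock arrays of B and C and 283 without the IL-4 array of C.

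The responses of the genotypes ran in parallel. Across 15378 genes, which are not independent replicates, the log2 changes correlated with r = 0.869 at 4 h and 0.876 at 18 h (rho 0.721 and 0.738), with slopes of Irf4-/- on Irf4+/- of 1.02 and 1.01, and r was 0.704 and 0.713 over probes without the filter on dim signals. Of all genes 77.2% at 4 h and 78.6% at 18 h had 1 sign in both genotypes, and within single experiments 69.9% to 75.7% and 66.4% to 78.2%. Retnla, Arg1 and the other genes called in either genotype numbered 730 at 4 h, all with 1 sign in both, and 752 at 18 h, 751 with 1 sign. Both genotypes shared 296 rises (8 by chance) and 233 falls at 4 h and 249 rises (7 by chance) and 188 falls at 18 h, and no gene called in both moved in opposite directions. A call in 1 genotype alone (125 in Irf4+/- and 76 in Irf4-/- at 4 h, 200 and 115 at 18 h) is no test of a difference.

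**Figure D2:**
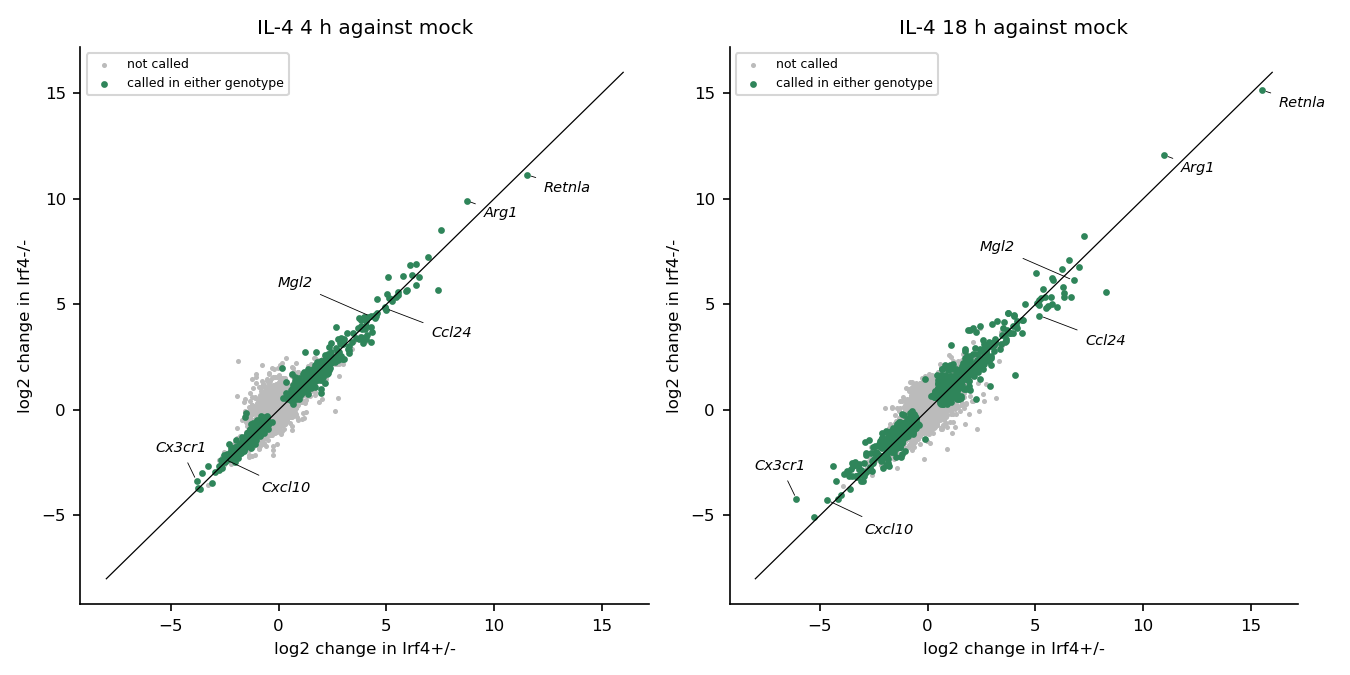
Log2 change with IL-4 in Irf4+/- (across) and Irf4-/- cells (up) for 15378 genes at 4 h and at 18 h. Genes called in either genotype are green, and the line marks equal change.

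Tested directly, the IL-4 response differed between the genotypes in 0 genes at 4 h and 0 at 18 h with limma (unadjusted p under 0.05 in 58 and 84 genes). The count was 0 with the block, and 2 at 18 h with the pool of cells as a random block. At 4 h the difference was lower in Irf4-/- cells for cholesterol biosynthesis (median -0.071, 0.016 in A and 0.098 in C, 0.058 with normexp), DNA replication (-0.12, 0.025 in A and 0.049 in C, 0.044 with normexp) and the unfolded protein response (-0.074, 0.16 with normexp). Each had adjusted p = 0.0491, but adjusted p = 0.988 with an estimated correlation. At 18 h it was lower for cholesterol biosynthesis (-0.15, 0.22 with normexp, adjusted p = 7.96e-04) and the unfolded protein response (-0.10, 0.36 with normexp, adjusted p = 0.00384). These had adjusted p = 0.902 with an estimated correlation. The same value (adjusted p = 0.902 with an estimated correlation) held for the IL-4 signature (-0.080, 0.012 in B and 0.031 in C, 0.032 with normexp, adjusted p = 0.00384), MHC class II (-0.23, 0.11 with normexp, adjusted p = 0.0192) and mitosis (-0.053, 0.16 in B, 0.28 with normexp, adjusted p = 0.0374). It held as well for macrophage identity, which was higher (0.19, adjusted p = 0.0292, but adjusted p = 0.902 with an estimated correlation). With the block oxidative phosphorylation was called at 4 h (median -0.036, 0.24 with normexp, adjusted p = 0.0496) and at 18 h (median 0.001, mean -0.019, tested lower, adjusted p = 0.0395). DNA replication was called at 18 h with the block (median -0.087, 0.35 with normexp, adjusted p = 0.0261). With block and estimated correlation these calls were lost (adjusted p = 0.953 at 4 h and 0.91 at 18 h). No fixed gene was called for its response. Ciita, whose protein switches on the MHC class II genes, had a value of -0.85 ± 1.08 at 18 h (adjusted p = 1).

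In Irf4-/- cells without IL-4, MHC class II genes, which present peptides to CD4 T cells, lay lower than in Irf4+/- cells in all 15 measured members (median -0.57). Their adjusted p was 1.13e-04, but adjusted p = 0.625 with an estimated correlation (0.232 with block and estimated correlation). No gene was called in limma (0, with 369 at an unadjusted p under 0.05, 0 with pool or slide as a random block). With the experiment as a block 5 genes were called. Among them were the class II chain genes H2-Aa (-1.14 ± 0.89, but ± 0.17 and adjusted p = 0.041 with the block) and, chosen after its values were seen, H2-Ab1 (-1.18, adjusted p = 0.0206 with the block). Ciita (-1.42 ± 0.76) and Cd74 (-0.78 ± 0.55), encoding the invariant chain, were not called. Conventional dendritic cell markers had a median of -0.46 (adjusted p = 0.0692, 0.0241 with the block, 0.391 with block and estimated correlation). DNA replication lay higher in Irf4-/- cells (median 0.40, 0.95 in B against 0.20 in A and 0.070 in C, adjusted p = 8.06e-10), as did ribosome biogenesis (0.40, -0.028 in C, adjusted p = 2.37e-06). These had adjusted p = 0.806 with an estimated correlation. Cholesterol biosynthesis (0.21, adjusted p = 7.16e-05), mitosis (0.13, adjusted p = 0.00937) and glycolysis (0.12, -0.024 with normexp, adjusted p = 0.0178) were higher, each also with adjusted p = 0.806 with an estimated correlation. Experiment B carried most of this, with 0.64, 0.34 and 0.35 against 0.065, 0.041 and 0.053 in A and 0.005, 0.074 and 0.003 in C. The unfolded protein response lay higher (0.13, -0.010 with normexp, adjusted p = 2.07e-04) and B-lineage markers lower (-0.40, 0.49 with normexp, adjusted p = 0.018). For both adjusted p = 0.625 with an estimated correlation. Calls added with the block were lysosome genes (-0.19, 0.054 in C, adjusted p = 0.0173 with the block), neutrophil markers (0.35, 1.32 in A, -0.14 in B and -0.044 in C, adjusted p = 0.0367 with the block) and sex-linked genes (0.42, -0.062 in B, adjusted p = 0.012 with the block). Oxidative phosphorylation was added too (0.033, -0.13 in A, -0.14 with normexp, adjusted p = 0.0499 with the block). With block and estimated correlation these 4 calls were lost (adjusted p = 0.391 for sex-linked genes and adjusted p = 0.696 for the others).

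After 4 h of IL-4, MHC class II genes again lay lower in Irf4-/- cells in all 15 members (median -0.73, adjusted p = 5.2e-08). That call was lost with an estimated correlation (adjusted p = 0.329 with an estimated correlation, 0.0454 with block and estimated correlation). Ciita stood at -1.45 ± 0.76, H2-Aa at -1.22 ± 0.89 and Cd74 at -0.73 ± 0.55. No gene was called in limma (0, with 119 at an unadjusted p under 0.05, 0 with pool or slide as a random block). With the block 4 were called, H2-Aa and, outside the rule for named genes, H2-Ab1, H2-Eb1 and the BAFF receptor gene Tnfrsf13c (adjusted p = 0.0243 each with the block). Ribosome biogenesis (median 0.35, 0.003 with slide as a block, where the test turned, adjusted p = 5.2e-08), DNA replication (0.25, adjusted p = 8.31e-06) and glycolysis (0.15, adjusted p = 0.0269) lay higher. These had adjusted p = 0.7 with an estimated correlation. Mitosis (0.15, adjusted p = 0.019) and cholesterol biosynthesis (0.065, -0.066 in A, adjusted p = 0.0492) were higher as well, with adjusted p = 0.742 with an estimated correlation. Dendritic cell markers (-0.13, 0.017 in C, adjusted p = 0.0364) and lipid uptake (-0.12, 0.031 in C, 0.14 with slide as a block, adjusted p = 0.0492) lay lower. So did lysosome genes (-0.16, 0.13 with slide as a block, adjusted p = 0.0309) and MHC class I genes (-0.22, 0.020 in C, 0.009 with scan day as a block, adjusted p = 0.0492), whose tests turned to a rise with normexp. These 4 lists had adjusted p = 0.7 with an estimated correlation. JAK-STAT genes lay lower (-0.20, 0.006 in C, adjusted p = 0.0492, but adjusted p = 0.329 with an estimated correlation). With the block cholesterol biosynthesis (adjusted p = 0.0687) and lipid uptake (adjusted p = 0.074) lost their calls.

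After 18 h of IL-4 the median gap in MHC class II genes was the widest of the 3 conditions, but no contrast tested it against that at 4 h. The list was called (median -0.93, -1.37 in A, -1.05 in B and -0.88 in C, adjusted p = 6.23e-10). That call was lost with an estimated correlation (adjusted p = 0.216 with an estimated correlation, 0.0372 with block and estimated correlation). Among 15378 genes, 4 were called, each with adjusted p = 0.0471. Cd300e, a myeloid activating receptor gene, was 2.28 ± 0.34 higher and the matrix gene Matn2 1.43 ± 0.21 higher in Irf4-/- cells. Papss2, whose enzyme makes the sulfate donor PAPS, was 1.64 ± 0.25 lower and the potassium channel gene Kcna3 1.63 ± 0.25 lower (at least 2.20-fold). Unadjusted p was under 0.05 in 465 genes, and 63 were called with the block (29 up, 34 down). Among these were Ciita (-2.27 ± 0.76, adjusted p = 1, 0.00162 with the block) and H2-Aa (-1.47 ± 0.89, adjusted p = 1, 0.00249 with the block). Cd74 (-0.93 ± 0.55, adjusted p = 1, 0.0406 with the block) and Itgax (-0.97 ± 0.23, adjusted p = 0.751, 0.0381 with the block) belonged there too. Also in the blocked set, and chosen after their values were seen, were H2-Ab1 (-1.59), H2-Eb1 (-1.58), H2-DMb2 (-1.40) and H2-DMa (-1.20). Of 25 alternatives only 1, the fit with the block, called Ciita, Cd74 and H2-Eb1, and only 2 called H2-Aa and H2-Ab1. Most of the 25 leave the pairing by experiment out, so this tally does not weigh the paired differences. Within the experiments A, B and C these were -2.25, -2.63 and -1.92 for Ciita and -0.72, -1.14 and -0.92 for Cd74. These fixed IL-4 genes were not called between the genotypes: Retnla -0.61 ± 0.59, Arg1 0.30 ± 0.74, Mgl2 -0.39 ± 0.33, Mrc1 0.61 ± 0.36, Ccl24 -1.34 ± 0.98 and Chil3 -0.037 ± 1.02 (adjusted p = 1 each, 0.121 or higher with the block). Retnla and Ccl24 lay lower and Mrc1 higher in all 3 experiments, so a difference in them is not excluded. DNA replication (median 0.32, 0.11 in A and -0.081 in C, adjusted p = 3.41e-04), ribosome biogenesis (0.35, 0 with slide as a block, adjusted p = 0.00269), neutrophil markers (0.53, adjusted p = 0.0439) and glycolysis (0.19, adjusted p = 0.0471) lay higher. For each of them adjusted p = 0.796 with an estimated correlation. Dendritic cell markers (-0.20, 0.025 in C, adjusted p = 0.0244), lipid uptake (-0.13, 0.18 in C, 0.15 with normexp, 0.20 with slide as a block, adjusted p = 0.0244) and lysosome genes (-0.12, 0.066 in C, 0.30 with normexp, 0.13 with slide as a block, adjusted p = 0.0471) lay lower. They too had adjusted p = 0.796 with an estimated correlation, and the call of lipid uptake was lost with the block (adjusted p = 0.0792). The count of 4 genes was 0 with normexp, with pool or slide as a random block and without experiment A. It was 0 without any 1 Irf4+/- array at 18 h and without the Irf4-/- array of A or of B, and 2 without that of C.

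**Figure D3:**
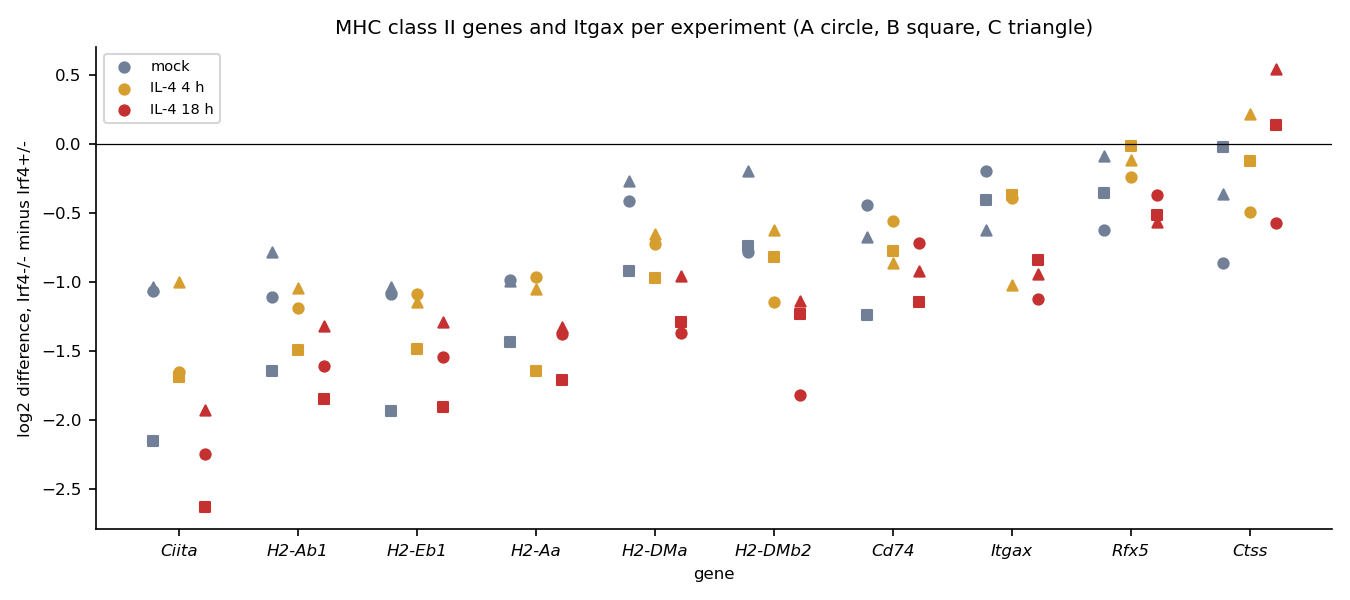
Log2 difference between Irf4-/- and Irf4+/- arrays of 1 experiment (1 pair per symbol) in mock, IL-4 4 h and IL-4 18 h, for 9 genes of MHC class II presentation and Itgax. Genes other than Ciita, H2-Aa, Cd74, Itgax and Ctss were picked after their values were seen, and points below 0 are lower in Irf4-/- cells.

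The main test, camera without the block, called 10 of the lists in no comparison. These were C-type lectins, CDK inhibitors, the IRF family and sex-linked genes. The others were the markers of monocytes, plasmacytoid dendritic cells, T and NK cells, basophils with mast cells and eosinophils, erythroid cells and fibroblasts. Their lowest adjusted p was 0.0598, for CDK inhibitors and fibroblasts between genotypes at 4 h. Some alternatives did call such lists, as the block did for sex-linked genes. With fry, C-type lectins were called at 4 h in Irf4+/- (adjusted p = 0.0174) and Irf4-/- cells (0.0426) and at 18 h in Irf4-/- cells (0.00723). With normexp, basophil (adjusted p = 0.0122) and erythroid markers (0.0377) were called for genotype at 18 h. Single members of these lists moved with IL-4. In Irf4+/- cells Pecam1, encoding an adhesion protein of endothelium and leukocytes, rose by 3.82 ± 0.44 at 4 h, the cell cycle inhibitor gene Cdkn2b by 2.87 ± 0.68, and the lectin gene Clec10a by 2.97 ± 0.21, while Clec4e fell by 2.40 ± 0.32 and the stem cell factor receptor gene Kit by 1.86 ± 0.45 (0.13 with normexp). At 18 h the histamine-forming enzyme gene Hdc fell by 1.66 ± 0.34 and the monocyte gene Plac8 by 2.14 ± 0.47. Macrophage identity genes moved both ways: Cd14 fell by 2.48 ± 0.23 at 18 h, and Cebpa (1.23 ± 0.27) and Fcgr3 (0.90 ± 0.16, 1.41 on its other kept probe) rose.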

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

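Results stand here because a direct test found a difference between groups or between times. Chosen only after the result was seen were the tests of scan day and of the H2 haplotype and of dendritic cells for MHC class II, that of alleles inside the 4 called genes, and that of experiment A for interferon-stimulated genes; all other tests were fixed before it.

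With IL-4 for 4 h, the response differed between the genotypes as a group in cholesterol biosynthesis, DNA replication and the unfolded protein response (adjusted p = 0.0491 each). With IL-4 for 18 h it differed in cholesterol biosynthesis (adjusted p = 7.96e-04), the IL-4 signature (adjusted p = 0.00384; median -0.28 in A, 0.012 in B and 0.031 in C), the unfolded protein response (adjusted p = 0.00384), MHC class II (adjusted p = 0.0192), macrophage identity (adjusted p = 0.0292) and mitosis (adjusted p = 0.0374). Each of these calls was lost with an estimated correlation (adjusted p = 0.988 at 4 h and 0.902 at 18 h) and with fry (adjusted p = 0.99 and 0.994). At 4 h cholesterol biosynthesis and DNA replication were called lower, but their medians were positive in A and in C, as given above. In mock cells, the baseline of that difference, Irf4-/- stood above Irf4+/- mostly in B. The medians there were 0.64 in B, 0.065 in A and 0.005 in C for cholesterol biosynthesis, and 0.945, 0.202 and 0.07 for DNA replication. In Irf4+/- cells 177 genes differed between 18 h and 4 h of IL-4.

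MHC class II genes lay lower as a group in Irf4-/- cells at 18 h in all experiments, with 14 of 15 members below 0 in A and in B and 11 in C. As given above, the call of this list was lost with an estimated correlation. A hypothesis is that loss of IRF4 may lower them through Ciita; the differences of Ciita and Cd74 were below 0 in 18 of 18 comparisons (3 experiments, 3 conditions, 2 genes, all from 3 pairs of pools and so not independent), but neither IRF4 protein nor that route was tested. Ciita lies on chromosome 16 and Cd74 on chromosome 18, outside H2 on chromosome 17. Another H2 haplotype therefore cannot lie inside these genes, which follows from their positions whatever their differences. Whether another haplotype lies inside the class II genes of H2 was not tested, so it cannot be told apart there. The other scan day of the Irf4-/- arrays of experiment A is excluded as the sole source. The median was -0.88 or lower in B and C, where both genotypes were scanned on the same day. At 18 h the genotypes lay on different slides in every experiment, so an effect of slide cannot be told apart from genotype. Sex-linked genes also differed between the genotypes in A and in C. Ddx3y lay at -0.33 to -0.28 in Irf4-/- and at -0.96 to -0.83 in Irf4+/- arrays of C. Xist stood higher in Irf4-/- arrays in A but lower in C. In B Ddx3y lay at 0.60 to 0.73 and 0.72 to 0.80, and the class II median there was -1.05. The sex makeup of the pools was not tested as a source. Fewer dendritic cells in the cultures cannot be told apart from lower expression per cell: the median of 13 dendritic cell genes was -0.20 (SD 0.44, 8 of 13 above background on all 6 arrays) against -0.93 for MHC class II, with Itgax at -0.97, Batf3 at -0.98, Dpp4 at -0.91, Zbtb46 at -0.30, Xcr1 at -0.20, Flt3 at 0.11 and Id2 at 0.015.

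The 4 genes called between the genotypes at 18 h (Cd300e, Matn2, Papss2, Kcna3) may mark the genotype or the alleles and arrays that came with it. None of the 4 lies on chromosome 13 (0 of 4), so strain alleles around Irf4 inside these genes themselves are excluded. Effects of such alleles on genes elsewhere were not tested, and for the calls with the block strain alleles cannot be told apart: the odds ratio for called genes within 20 Mb of Irf4 was 2.53 at 18 h (2 of 199 genes, 95% interval 0.298 to 9.68, exact p = 0.194). Over any of the 3 genotype contrasts it was 2.45 (0.288 to 9.35, exact p = 0.204), and without the block 0 (0 of 199). The other scan day in experiment A cannot be told apart either: the median difference in B and C was 1.06 times that in A (4 genes, 0.835 for the 63 genes called with the block), but genes alike in A, B and C are those that the test calls.

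Interferon-stimulated genes lay lower at 18 h in all experiments of Irf4+/- cells, with medians of -2.46 in A, -0.83 in B and -1.20 in C and all 41 members below 0 in each (adjusted p = 4.82e-21, but adjusted p = 0.343 with an estimated correlation). A high interferon signal in the mock arrays of A alone is excluded as the sole source, as the higher of the medians in B and C was -0.83. IL-4 itself could lower them in both genotypes, as the medians in Irf4-/- cells were -2.30, -0.81 and -0.97.

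Other splits of the same 6 arrays into groups of the same sizes were tested. Of 10 splits, 1 (the real one) reached the real count for IL-4 at 4 h and 18 h in Irf4+/- cells (654 and 637 genes), in Irf4-/- cells (605 and 552), for 18 h against 4 h (177) and for genotype at 18 h (4), where the highest other count was 0. For genotype in mock and at 4 h 10 of 10 splits reached the real count of 0 (highest other 0), which any split must reach, so this tells nothing. Among the splits that part each pair, the highest other count with the block was 0, against real counts of 2803, 2386, 2807, 2862, 5, 4, 63 and 1770 (IL-4 in Irf4+/- and Irf4-/- cells, genotype in mock, at 4 h and at 18 h, 18 h against 4 h). So few splits exist that no share under 0.05 can be reached. For the difference of responses 100 of the 200 possible splits were run, and all 100 reached the real count of 0 at 4 h and at 18 h. Any split must reach a count of 0, so this tells nothing either. The highest other count was 0 at 18 h and 1299 at 4 h, in a split that follows the experiments (mock A, A, B against B, C, C, and IL-4 the opposite way).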

How the results depend on the processing

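Directions held under nearly all settings, but under many of them they could hardly turn. Of 7251 values of named genes called by limma, recomputed under an alternative, 6281 kept direction and call, 957 kept direction but lost the call and 13 reversed, all with normexp. The block, pool as a random block, an intensity trend, only the groups of a contrast and every probe on its own alter the spread and hardly the log2 change. The largest rises and falls were also picked for 1 sign in all experiments, so leaving out 1 array could hardly reverse them. Of 19912 values of named genes not called, 454 were called. For gene lists, 1393 of 1936 called values stayed, 510 lost the call and 33 reversed, and of 5974 values not called, 280 were called and 45 reversed. The IL-4 signature and chemokine receptors stayed called under 22 of 22 alternatives in both genotypes at both times. MHC class II between genotypes at 18 h was called under 19 of 22 (median -1.10 to -0.71, adjusted p from 1.61e-19 to 0.777), at 4 h under 19 of 22 (-0.97 to -0.33, adjusted p up to 0.948) and in mock under 18 of 22 (-0.60 to -0.086, adjusted p up to 0.873). Interferon-stimulated genes at 18 h in Irf4+/- cells were called under 19 of 22 (-1.64 to -1.04, adjusted p from 4.23e-27 to 0.366), and the lower IL-4 signature in the response difference at 18 h under 15 of 22 (-0.16 to 0.032, adjusted p from 2.6e-04 to 0.997). For interferon-stimulated genes the estimated correlation was 0.857, and their call was lost with it. Of the 4 genes called between genotypes at 18 h, Cd300e was called under 9 of 25 alternatives (0.90 to 2.56), Matn2 under 9 of 25 (0.17 to 1.69), Papss2 under 6 of 24 (-1.84 to -0.49) and Kcna3 under 3 of 24 (-1.81 to -0.37). Of the MHC class II genes called there with the block, Ciita (-2.88 to -1.83), Cd74 (-1.38 to -0.49) and H2-Eb1 (-2.09 to -1.14) were called under 1 of 25. H2-Aa (-2.18 to -0.95) and H2-Ab1 (-2.08 to -1.19) were called under 2 of 25. Most of these alternatives leave the pairing by experiment out. The blocked fit ended no call of a gene, added calls for 112 values of named genes, and changed no list call other than those given. Folds of genes dim in 1 group are lower bounds, and genes that were not above background on all 18 arrays gave no value under that filter. For the changes below the cause was not tested unless one is named.

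Planned normexp gave 233, 243, 221 and 142 genes for IL-4 (4 h and 18 h in Irf4+/-, then in Irf4-/-), 0 for genotype at 18 h and 14 for 18 h against 4 h. It called 14 lists for genotype in mock, 17 for genotype at 18 h, and 19 and 17 for the response difference at 4 h and 18 h. Up to 8 spots per array far dimmer than their local background drew its fit, and the range from the 5th to the 95th percentile fell to 3.63 on 1 array. With those spots left out the range was 7.33 to 8.64, no value reversed, and the only count outside 1.5 times was 0 for genotype at 18 h, so these spots account for the reversals below. The median of all genes moved from -0.023 to 0.18 with planned normexp at 4 h in Irf4+/- cells and to 0.15 at 18 h.

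Reversed with normexp at 4 h in Irf4+/- cells were Kit (0.13) and Txk (0.19). At 18 h these were Cxcl1 (0.38), Cxcl11 (1.03), Cxcl9 (1.05), Dscam (0.015), Fpr1 (0.13), Tlr3 (0.09) and Tlr5 (0.32). Lists reversed there, with medians, were cholesterol biosynthesis (-0.26), lipid uptake (-0.025), oxidative phosphorylation (-0.081), arginine metabolism (-0.27), the unfolded protein response (-0.18), lysosome (-0.31) and, by its test alone, immediate early genes (0.21). Between 4 h and 18 h these were Cxcl9 (0.69), Dscam (0.35), Nkd2 (0.41), Ppm1n (0.58), oxidative phosphorylation (-0.17), DNA replication (0.010), the NRF2 response (-0.12) and lysosome (-0.21).

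For lists the direction is that of the test against all other genes, so a printed median can keep the sign it had. Lists reversed with normexp for genotype in mock were, by its test alone, interferon-stimulated genes (-0.30, -0.13 before), and glycolysis (-0.024), oxidative phosphorylation (-0.14), the unfolded protein response (-0.010) and B-lineage markers (0.49). For genotype at 4 h these were, by their tests alone, MHC class I (-0.11) and lysosome (-0.073), and at 18 h lipid uptake (0.15), oxidative phosphorylation (0.41), lysosome (0.30), basophil (-1.10) and erythroid markers (-0.93). In the response difference at 4 h these were MHC class I (0.36), interferon-stimulated genes (0.23), Toll-like receptors (0.14), cholesterol biosynthesis (0.058), lipid uptake (0.15), glycolysis (0.28), oxidative phosphorylation (0.24), DNA replication (0.044) and mitosis (0.15). Also reversed there were CDK inhibitors (0.25), ribosome biogenesis (0.20), the unfolded protein response (0.16), lysosome (0.30) and the markers of B-lineage (-1.03), T and NK (-1.29), basophil (-0.97) and erythroid cells (-0.68). In the response difference at 18 h these were the IL-4 signature (0.032), MHC class II (0.11), MHC class I (0.70), interferon-stimulated genes (0.44), cholesterol biosynthesis (0.22), lipid uptake (0.36), glycolysis (0.55), oxidative phosphorylation (0.56), DNA replication (0.35) and mitosis (0.28). Also reversed there were CDK inhibitors (0.47), ribosome biogenesis (0.34), the unfolded protein response (0.36), lysosome (0.64) and the markers of B-lineage (-1.66), T and NK (-1.89), basophil (-1.48), erythroid (-1.39) and fibroblast cells (-1.55).

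The authors' deposited values gave 3068 and 2690 genes at 4 h and 18 h in Irf4+/-, 1092 and 979 in Irf4-/-, 5 for genotype in mock, 7 at 18 h and 438 for 18 h against 4 h. Their Irf4+/- mock columns are 0 throughout, which removes the spread of that group. Lists called were 6 for genotype at 4 h and 0 for the response difference at 4 h. Quantile normalization gave 2 genes for genotype at 18 h, 7 lists for genotype at 4 h and 0 for the response difference at 4 h, and median scaling 0 lists for that difference. Without the filter on dim probes 0 genes and 5 lists were called for genotype at 18 h and 0 lists for the response difference at 4 h. With probes above background on all 18 arrays these were 2 genes for genotype at 18 h and 0 lists for that difference. The mean of all probes gave 5 lists for genotype at 18 h, every probe on its own 0 genes there, and an intensity trend 2 genes. Array weights gave 1503 and 1564 genes at 4 h and 18 h in Irf4-/-, with 7, 3 and 0 lists for genotype at 4 h, genotype at 18 h and the response difference at 4 h.

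The replicate block gave 2803, 2386, 2807 and 2862 genes for IL-4, in the order above, 5, 4 and 63 for genotype in mock, at 4 h and at 18 h, 1770 for 18 h against 4 h, and 13 lists for genotype in mock. The pool of cells as a random block gave 4770, 4049, 5357 and 5596 for IL-4, 0 for genotype at 18 h, 2 for the response difference at 18 h, 3552 for 18 h against 4 h, and 13 lists for genotype in mock. Slide as a block gave 4528, 2727, 3203 and 3700 for IL-4, 3 each for genotype in mock and at 4 h and 1976 for 18 h against 4 h. It leaves the genotypes compared through the 1 slide that held both. Slide as a random block gave 5058, 3453, 4179 and 4278, 0 for genotype at 18 h, 2921 for 18 h against 4 h, and 0 lists for the response difference at 4 h. Scan day as a block gave 1694, 1416, 1675 and 1397, 1 for genotype in mock, 868 for 18 h against 4 h, and 0 lists for that difference. Reversed with slide as a block were lipid uptake (0.16 in mock, 0.14 at 4 h, 0.20 at 18 h between genotypes), ribosome biogenesis (0.003 at 4 h, 0 at 18 h), lysosome (0.13 at both), and at 4 h costimulation (-0.48), inflammatory cytokines (-0.35) and osteoclast markers (-0.32). Reversed with scan day as a block were MHC class I (0.009 at 4 h), interferon-stimulated genes (0.14 at 4 h, 0.29 at 18 h) and lysosome (-0.001 at 4 h, 0.043 at 18 h), and with slide as a random block lipid uptake (0.003 at 4 h).

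Without experiment A, 0 genes and 3 lists were called for genotype at 18 h, 6 lists for genotype at 4 h and 1 for the response difference at 4 h. Oxidative phosphorylation reversed for genotype at 18 h (0.17, and 0.17 with the block too). With the block added, the counts without A were 1688, 1419, 1594 and 1885 genes for IL-4, 1 for genotype at 18 h and 753 for 18 h against 4 h, with 7 lists for genotype at 4 h and 1 and 3 for the response difference at 4 h and 18 h. With only the groups of a contrast, which leaves fewer arrays for the spread, they were 209, 166, 346 and 254 for IL-4, 0 for genotype at 18 h and 0 for 18 h against 4 h, with 5 lists for genotype at 18 h and 0 for the response difference at 4 h. Leaving out each array in turn gave 424 to 513, 407 to 642, 287 to 554 and 283 to 490 genes for IL-4, 0 to 2 for genotype at 18 h, 88 to 117 for 18 h against 4 h, and 0 to 0 elsewhere.

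With an estimated correlation 2, 3, 2 and 2 lists were called for IL-4, 4 for 18 h against 4 h and 0 for each genotype contrast and response difference. With the block as well, 2 were called for each IL-4 contrast, 0, 1 and 1 for genotype in mock, at 4 h and at 18 h, 0 for each response difference and 0 for 18 h against 4 h. Fry gave 0 for each genotype contrast and response difference and 5 for 18 h against 4 h, and for change in either direction 18 at 4 h in Irf4+/-, 15 and 16 in Irf4-/- and 0 for each genotype contrast and response difference. With fry the C-type lectins turned at 18 h in Irf4-/- cells (median -0.28).

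For the correlation of responses across genes, dropping the filter on dim probes gave r = 0.704 and 0.713 and rho = 0.562 and 0.567 at 4 h and 18 h, and genes called in either genotype gave r = 0.988 and 0.976 and rho = 0.977 and 0.963. Without each replicate in turn r was 0.830 to 0.843 at 4 h and 0.826 to 0.870 at 18 h, rho 0.683 to 0.696 and 0.663 to 0.748, and the slope 0.982 to 1.07 and 0.975 to 1.10.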

Other observations

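With the experiment as a block, further genes separated the genotypes, picked after their values were seen. In mock cells H2-Eb1 lay 1.35 and Arrdc5 1.28 lower in Irf4-/- cells and the anion exchanger gene Slc26a4 2.33 higher. At 18 h the cytochrome gene Cyp1b1 lay 2.36 and the semaphorin gene Sema6d 1.84 lower. Mterf2 lay 1.58, the paired receptor gene Pilra 1.48, the lipoxygenase gene Alox8 1.42 and the eotaxin receptor gene Ccr3 0.97 higher.

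Genes of the sex chromosomes differed between experiments. Xist lay at -8.52 to -7.91 on all arrays of B (log2 level), at 1.23 to 2.89 in A and at 2.44 to 4.54 in C. In A the Irf4+/- arrays (1.23 to 1.95) stood below the Irf4-/- arrays (2.35 to 2.89). In C the Irf4+/- arrays (4.11 to 4.54) stood above the Irf4-/- arrays (2.44 to 2.90). Ddx3y, on the Y chromosome, lay at 0.60 to 0.80 in B, at -0.67 to -0.39 in Irf4+/- and -0.22 to 0.24 in Irf4-/- arrays of A, and at -0.96 to -0.83 and -0.33 to -0.28 in C. Per the labels, every pool was made from cells of both sexes, which the Xist levels of B do not show.

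Over the 15326 genes with a value on every array the 1st principal component held 37.6% of the variance and followed the experiment (R2 0.796), the 2nd held 20.1% and followed the treatment (R2 0.759), and genotype stood highest on the 6th (R2 0.577 of 3% of the variance). The fit of the spike-in controls had R2 0 on the 3 Irf4-/- arrays of B, 0.817 to 0.878 on the Irf4+/- arrays of B and 0.944 to 0.996 on all others. No hypothesis was tested on these values.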
